A study of Homo sapiens with 6 samples.

How the data were processed

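RNA was measured by stranded poly(A) RNA sequencing (TruSeq Stranded mRNA, per the labels' protocols) in 6 libraries of HEK293T cells, 3 transfected with a plasmid labelled ERbeta and 3 with an empty vector, EV_Ctrl. Per the submitters' processing notes, TopHat2, featureCounts and DESeq2 were used with the genome build hg38. Their versions, the gene annotation and the strand setting of the counting are not given in the sources used here. Reads from a gene and from an antisense or overlapping partner are therefore treated as uncertain.

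The deposited count table holds the authors' raw whole-number read counts per gene and library, with versioned Ensembl identifiers for 64299 genes, of which 33813 had 0 reads in all 6 libraries. A symbol was found for 40995 identifiers by matching the identifier without its version. The table held 0 reads in entries that name no gene and 0 columns outside the 6 libraries. A second deposited table holds the authors' own comparison of ERbeta with the empty vector. Per the file headers it gives a mean signal (mean count after DESeq2 size factors), a log2 fold change, its standard error and Wald statistic as scores without a fixed range, and p-values before and after adjustment. That table was used to set the authors' values beside those computed from the counts, never as input to a test.

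Groups were taken from the labels. The labels name replicates 1 to 3 in each group and do not say that they came from separate cultures, so p-values measure the spread between these libraries, which may be technical. No pair of libraries within a group agreed within counting noise. A chi-square statistic per degree of freedom ranged from 4.77 for EV_Ctrl 1 and 3 to 38.7 for EV_Ctrl 2 and 3, so all 6 libraries were counted separately. Intervals given for pooled read ratios are exact binomial 95% intervals and cover counting error only, since reads without molecular identifiers are not independent molecules.

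Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 16243 genes holding 99.8% of the reads of each library. Counts were normalised by the trimmed mean of M values (TMM) and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with group as the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors of log2 fold changes were computed from the quasi-likelihood F statistic. The level of a gene is its TMM-normalised CPM (counts per 1e6 counts of the library), given as mean ± SD. The biological coefficient of variation was 17.5%.

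Of the gene lists, 19 were fixed before the data were examined, as were the test, the alternatives and the rule for named genes. Each list was tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, which asks whether its members were higher or lower relative to the other genes, and the p-values were adjusted over the 19 lists. Camera was repeated with the correlation estimated from the libraries. In that setting camera also uses fewer degrees of freedom, so a larger p there need not mean that the members were correlated. The test fry, which asks whether the members of a list move one way on balance without comparing them with other genes, was run beside it. Members passing the threshold were counted over all genes and adjusted over the list alone.

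Named genes were the 12 with the largest increase and the 12 with the largest decrease among genes passing the threshold, with a mean log2 CPM of at least 1 and no overlap between groups (none passed). To these came up to 4 members of each list with the smallest p-values, and HSPA5, DNAJB9, HERPUD1, DDIT3, ATF4, XBP1, HSPA1A, DNAJB1, ESR1 and ESR2 in any case. Other genes are said to have been chosen after their values were seen.

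Alternatives planned in advance were DESeq2 1.42.0 size factors, library size only, no filter on low counts, a filter of at least 1 CPM in all libraries, DESeq2's test, limma-voom, robust empirical Bayes, a replicate block, counts thinned to the smallest total, an adjusted p under 0.01, and leaving out each library. A correction for GC content was added after the data were seen. A loess curve (span 0.5) of log2 CPM on the GC content of each gene's longest transcript in GENCODE 29 was fitted per library and entered as an offset. A GC value was found for 99.1% of the tested genes, leaving 16091. Also added was a fit without EV_Ctrl replicates 1 and 3, in which the lone EV_Ctrl library is assumed to vary like the ERbeta libraries. Coordinates are from GENCODE 29 on GRCh38, the build that the notes name as hg38. Figures were drawn with matplotlib.

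The steps were tested on simulated counts for the 16243 genes at the depths of these 3 ERbeta and 3 EV_Ctrl libraries. Changed genes were drawn only from genes outside the lists with a mean log2 CPM above 1, so the recovery rates do not cover genes at lower levels. Without a GC trend, edgeR's test recovered 5.97% of genes changed 1.5-fold, 67.2% of those changed 2-fold and 98.5% of those changed 4-fold, with 10 false calls. With the libraries' own GC trends added, it recovered 41.8% of the genes changed 2-fold with 33 false calls, and the GC offset brought this to 68.7% and 14. The added trend was the same loess curve that the offset removes, and the dispersions were those of the fit without GC correction. This therefore does not show whether the offset corrects too much in the real libraries. In a separate simulation of the same design with 16036 genes and the ER chaperone list raised 1.3-fold, camera gave that list an adjusted p of 3.3e-12 and called 0 of the 18 other lists. Genes were drawn independently of each other in it, so it does not test false calls of lists whose members are correlated.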

Results

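The data comprise 6 RNA sequencing libraries of HEK293T, a transformed human embryonic kidney line that is widely used for plasmid transfection. The sample labels name HEK293T, while the series description names HEK293, and the name of the sample labels is used here. In 3 libraries the cells had received a plasmid labelled ERbeta or ER-β, and in 3 an empty vector, EV_Ctrl, with a lipid-based reagent. The series concerns how the endoplasmic reticulum (ER) handles proteins prone to form amyloid. The labels do not define ER-β; from background knowledge of the study it is taken here as an artificial β-sheet protein directed into the ER, not estrogen receptor beta. Its level was not analysed here because the gene table covers human genes. Total counts were 16531368, 15821501 and 13149304 in ERbeta 1, 2 and 3, and 6833442, 27101644 and 10806375 in EV_Ctrl 1, 2 and 3. Between 21901 and 25777 genes had at least 1 read, and mitochondrially encoded genes took 2.60% to 3.93% of the counts. The libraries did not fall apart by group alone. The first principal component, 60.8% of the variance of log2 CPM, placed EV_Ctrl 1 and 3 at 44.7 and 41.6, EV_Ctrl 2 at -13.9 and the ERbeta libraries between -42.1 and -13.9.

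The design holds a single comparison, ERbeta against empty vector, which asks how cells respond to that protein. Genes of the ER unfolded protein response named in advance are given first. HSPA5, which encodes BiP, the main Hsp70 chaperone of the ER lumen, was at 878 ± 9.05 CPM in ERbeta and 522 ± 18.9 CPM in EV_Ctrl (SD, n = 3 each), a log2 fold change of 0.75 with a standard error of 0.08. HERPUD1, an ER membrane protein of the degradation machinery, was at 76.1 ± 16.6 against 34.3 ± 4.25 CPM, and DNAJB9, an ER co-chaperone of BiP, at 33.9 ± 3.57 against 15.2 ± 4.98 CPM. DDIT3, the stress transcription factor CHOP, was at 47.9 ± 3.88 against 27.5 ± 1.86 CPM. XBP1, a transcription factor whose mRNA is spliced by the ER sensor IRE1, was at 133 ± 4.91 against 88.4 ± 3.65 CPM, a log2 fold change of 0.59 that was 0.33 after a correction for GC content (described below). For each of these 5 genes all 3 ERbeta libraries lay above all 3 EV_Ctrl libraries.

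None of these differences passed the test over all genes. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 16243 genes passed the threshold of 0.05, and the smallest adjusted p was 0.13, that of HSPA5 among others. The adjusted p was 0.256 for HERPUD1 and XBP1, 0.333 for DNAJB9 and 0.235 for DDIT3. At an unadjusted p under 0.05 there were 2018 genes, 1550 higher and 468 lower in ERbeta. DESeq2 called 52 genes, 51 higher and 1 lower, and limma-voom called 1. DESeq2's adjusted p was 2.7e-08 for HSPA5, 0.000107 for HERPUD1, 0.000146 for DDIT3, 0.0019 for XBP1 and 0.00496 for DNAJB9. The call count depended on a single control library: without EV_Ctrl 2, edgeR's test called 2324 genes, 2198 higher and 126 lower. With GC correction as well it called 1650, 1054 higher and 596 lower. Leaving out any other library gave 0 calls, with 808 to 1982 genes at an unadjusted p under 0.05. The groups did not overlap for 18.7% of genes, 1658 higher and 1378 lower, where chance gives 10% for 3 against 3.

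HSPA5 lies on chromosome 9 (125234853 to 125241330, minus strand), HERPUD1 on chromosome 16 (56932048 to 56944863, plus strand), DNAJB9 on chromosome 7 (108569568 to 108574850, plus strand), DDIT3 on chromosome 12 (57516588 to 57521737, minus strand) and XBP1 on chromosome 22 (28794555 to 28800597, minus strand) of GRCh38. All are protein-coding genes, and their counts are sums over annotated exons, so the spliced and unspliced forms of XBP1 mRNA were not told apart.

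**Figure D1:**
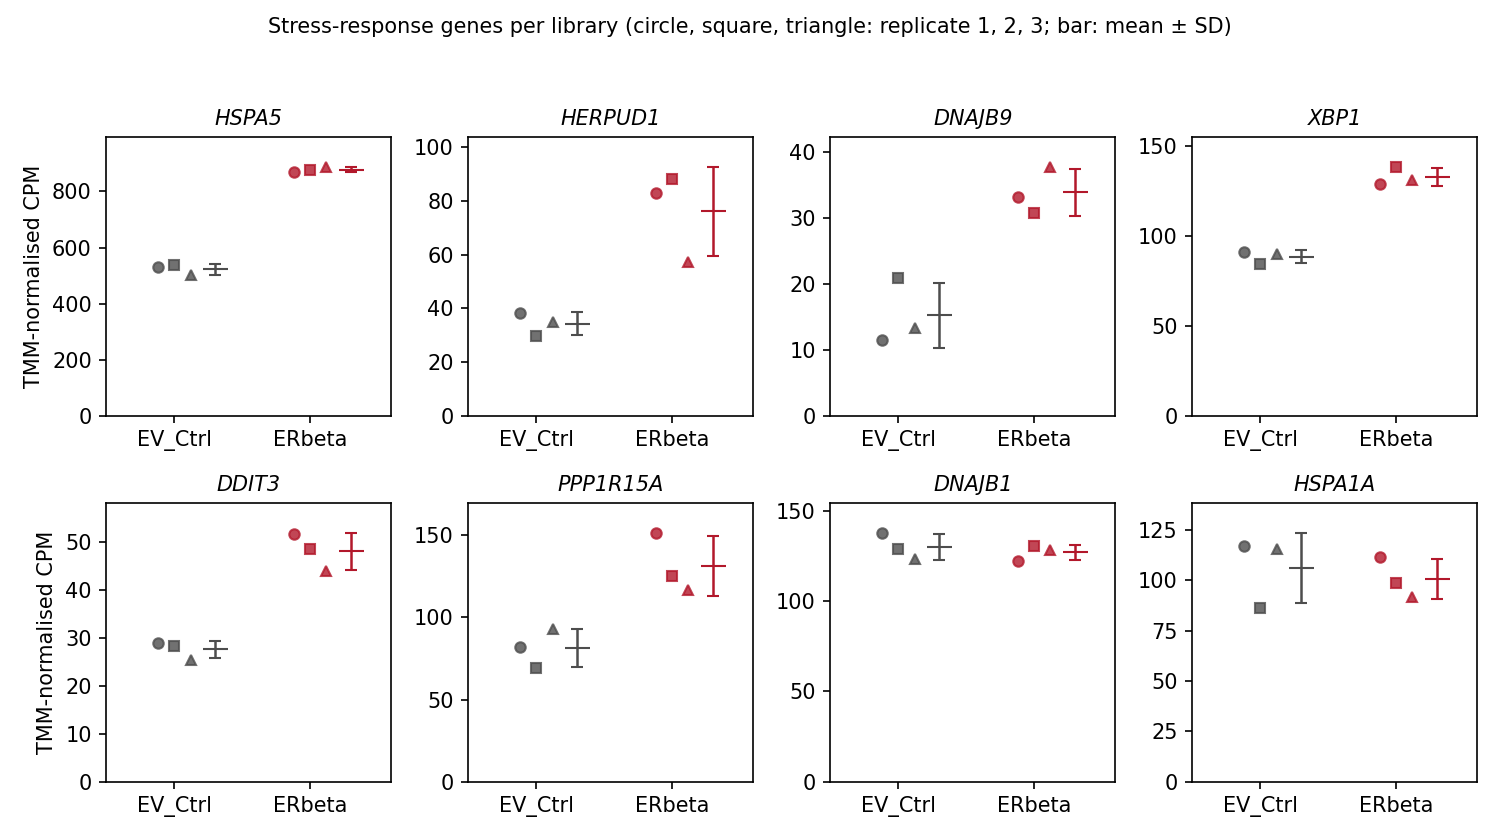
TMM-normalised CPM (vertical axis, from 0) of 8 stress-response genes in the EV_Ctrl (grey) and ERbeta (red) libraries, each symbol 1 library and each bar the mean ± SD of 3. HSPA5, at 878 against 522 CPM, and the other ER stress genes lay higher in all ERbeta libraries, while the ranges of DNAJB1 (127 against 130 CPM) and HSPA1A (101 against 106 CPM) overlapped.

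ER chaperones and folding enzymes were higher as a group. Of 26 measured members, 25 had a positive log2 fold change, the median was 0.34, and 16 did not overlap between groups. With p-values adjusted over the list alone 11 rose and 15 did not pass, while 0 passed over all genes. Besides HSPA5 and DNAJB9 they included DNAJB11, a BiP co-chaperone, at 0.48 ± 0.10 (log2 fold change ± SE, edgeR) and ERO1B, an oxidase of disulfide formation, at 0.67 ± 0.15. HSP90B1, the ER form of Hsp90, at 0.83 ± 0.23, and HYOU1, a nucleotide exchange factor for BiP, at 0.37 ± 0.09, were chosen after their values were seen. HSP90B1 was at 1208 CPM in EV_Ctrl 2, against 714 and 640 in EV_Ctrl 1 and 3 and 1476 to 1555 in ERbeta. With GC correction HSP90B1 was at 0.59 and HYOU1 at 0.48. Camera gave the list an adjusted p of 9.05e-09, and the adjusted p was 0.201 with an estimated correlation. In fry the adjusted p was 0.00816. The mean log2 CPM of the list was 7.05 to 7.14 in the ERbeta libraries, 6.81 in EV_Ctrl 2 and 6.66 and 6.65 in EV_Ctrl 1 and 3. The number adjusted over the list alone was 4 without ERbeta 1, 2 without EV_Ctrl 1, 7 without EV_Ctrl 3, 1 without both of these controls and 7 with library size only. After a correction for GC content DNAJB11 was at -0.02 and ERO1B at 0.13, whereas HSPA5 was at 0.71 and DNAJB9 at 0.83. In EV_Ctrl 2, whose GC trend lay near that of ERbeta 1 and 2, DNAJB11 was at 95.2 CPM, against 118 and 127 in those libraries. ERO1B was at 60.7 CPM, against 77.3 and 75.2. With a single such control library, this does not settle whether the correction removed more than the GC trend from these genes.

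ER-associated degradation, the removal of misfolded proteins from the ER, was led by a pair of genes. Adjusted over the list alone, 2 of 27 measured members rose, 25 did not pass, and 0 passed over all genes. These were HERPUD1, at a log2 fold change of 1.16 ± 0.19, and SEL1L, the partner of the HRD1 ubiquitin ligase, at 0.75 ± 0.18. DERL3 was at 0.47 ± 0.13 and UBE2J1 at 0.42 ± 0.15 (0.27 without ERbeta 3), neither passing. In fry the list's adjusted p was 0.00816. Camera's adjusted p was 0.0368 with a median log2 fold change of 0.08, and adjusted p = 0.299 with an estimated correlation. That correlation was -0.015, below the preset 0.01, yet camera's unadjusted p went from 0.0116 to 0.0472. Correlation between members therefore does not account for this rise. The call ended without ERbeta 2 (adjusted p 0.0531) or EV_Ctrl 2 (0.353), with library size only (0.122) and with the replicate block (0.0579). The members adjusted over the list alone numbered 1 without ERbeta 1, EV_Ctrl 1 or EV_Ctrl 3, 1 without both of these controls, 1 with the replicate block and 9 without EV_Ctrl 2. After GC correction SEL1L was at 0.36 and UBE2J1 at 0.06, with HERPUD1 at 1.18 and DERL3 at 0.61.

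Other lists covered protein entry into the ER and transport out of it. For translocation and N-glycosylation, 31 of 34 measured members had positive log2 fold changes with a median of 0.20, 0 passed over all genes or adjusted over the list alone, and camera gave an adjusted p of 0.000217 (adjusted p = 0.56 with an estimated correlation, and 0.127 in fry). Its members with the smallest p-values were SRP9 of the signal recognition particle at 0.74 ± 0.18, TRAM1 at 0.92 ± 0.24, SSR1 at 0.61 ± 0.21 and SEC63 at 0.68 ± 0.24 (1.03 without EV_Ctrl 2). After GC correction the list's adjusted p was 0.002, and adjusted p = 0.382 with an estimated correlation, and SRP9 was at 0.23, TRAM1 at 0.46, SSR1 at 0.32 and SEC63 at 0.33. The list's mean log2 CPM in EV_Ctrl 2 was 6.79, near the 6.82 to 6.94 of the ERbeta libraries, against 6.48 and 6.41 in EV_Ctrl 1 and 3. Without EV_Ctrl 1 and 3 the list's adjusted p was 0.0715. For ER to Golgi transport 23 of 30 members were positive with a median of 0.09, 0 passed in either count, and camera's adjusted p was 0.0368 (adjusted p = 0.864 with an estimated correlation). SEC24D and SEC24A, coat proteins of COPII vesicles, were at 0.49 ± 0.12 and 0.44 ± 0.12, BET1 at 0.52 ± 0.15 and LMAN1, a cargo receptor, at 0.96 ± 0.34 (1.49 without EV_Ctrl 2). This call ended without ERbeta 3 (0.131), without EV_Ctrl 2 (0.258), with library size only (0.122), with the replicate block (0.0579) and in fry (0.127). It also ended with GC correction (0.366), where SEC24A was at 0.02, BET1 at -0.004 and LMAN1 at 0.63.

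Targets of the PERK-ATF4 branch, through which the ER sensor PERK and amino acid shortage raise genes of amino acid supply and stress recovery, were higher together. Of 33 measured members 30 were positive, the median was 0.25, 22 did not overlap between groups, and 8 rose when adjusted over the list alone while 25 did not pass. Over all genes 0 passed. The smallest p-values were those of DDIT3, at 0.80 ± 0.12, the cystine transporter gene SLC7A11 at 1.04 ± 0.22, PPP1R15A (GADD34, a regulatory subunit of an eIF2α phosphatase) at 0.69 ± 0.15 and SLC3A2, the shared heavy chain of amino acid transporters, at 0.51 ± 0.12. ATF4 itself was at 431 ± 36.3 against 383 ± 30.9 CPM, a log2 fold change of 0.17 ± 0.11 that did not pass (0.29 after GC correction, not passing either). In fry the list's adjusted p was 0.00816. Camera's adjusted p was 1.09e-07, and adjusted p = 0.299 with an estimated correlation. Without EV_Ctrl 2 it was 0.0581. The count adjusted over the list alone was 0 without ERbeta 1, 2 without ERbeta 2, 5 without ERbeta 3, 1 without EV_Ctrl 1, 5 without EV_Ctrl 2 and 2 without EV_Ctrl 3. It was 1 with the replicate block, 2 with library size only, 2 without both EV_Ctrl 1 and 3 and 4 with DESeq2 size factors. With GC correction it was 21, 20 higher and 1 lower, among them all 8 of the uncorrected test, and SLC7A11 was at 0.42. The list's mean log2 CPM was 6.65 to 6.75 in the ERbeta libraries and 6.38 to 6.42 in the EV_Ctrl libraries.

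The cytosolic heat shock response was measured beside the ER lists. Of 32 measured chaperones and co-chaperones 23 were positive with a median log2 fold change of 0.13, and 0 passed over all genes or adjusted over the list alone. The stress-inducible Hsp70 gene HSPA1A was at 101 ± 9.98 against 106 ± 17.3 CPM, a log2 fold change of -0.07 ± 0.15. Its near-identical neighbour HSPA1B, named after its values were seen, was at -0.05 ± 0.13, and reads may be split between these copies. The Hsp40 gene DNAJB1 was at -0.04 ± 0.10. All 3 signs turned with GC correction, to 0.08 for HSPA1A, 0.10 for HSPA1B and 0.05 for DNAJB1. The members with the smallest p-values were DNAJB4 at 0.85 ± 0.25, CHORDC1 at 0.87 ± 0.29, DNAJA1 at 0.50 ± 0.20 and CACYBP at 0.48 ± 0.21, and none passed. Without EV_Ctrl 2 CHORDC1 was at 1.31, DNAJA1 at 0.79 and CACYBP at 0.79. After GC correction DNAJB4 was at 0.15, CHORDC1 at 0.26, DNAJA1 at 0.28 and CACYBP at 0.13. Camera called the list higher with an adjusted p of 0.0199, and adjusted p = 0.894 with an estimated correlation. With GC correction the adjusted p was 0.000219, and adjusted p = 0.567 with an estimated correlation. The call also ended in fry (0.207), without ERbeta 2 (0.0508), without EV_Ctrl 3 (0.119) and without both EV_Ctrl 1 and 3 (0.541). The list's mean log2 CPM in EV_Ctrl 2, 8.002, lay within the ERbeta range of 7.99 to 8.10, against 7.73 and 7.63 in EV_Ctrl 1 and 3.

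**Figure D2:**
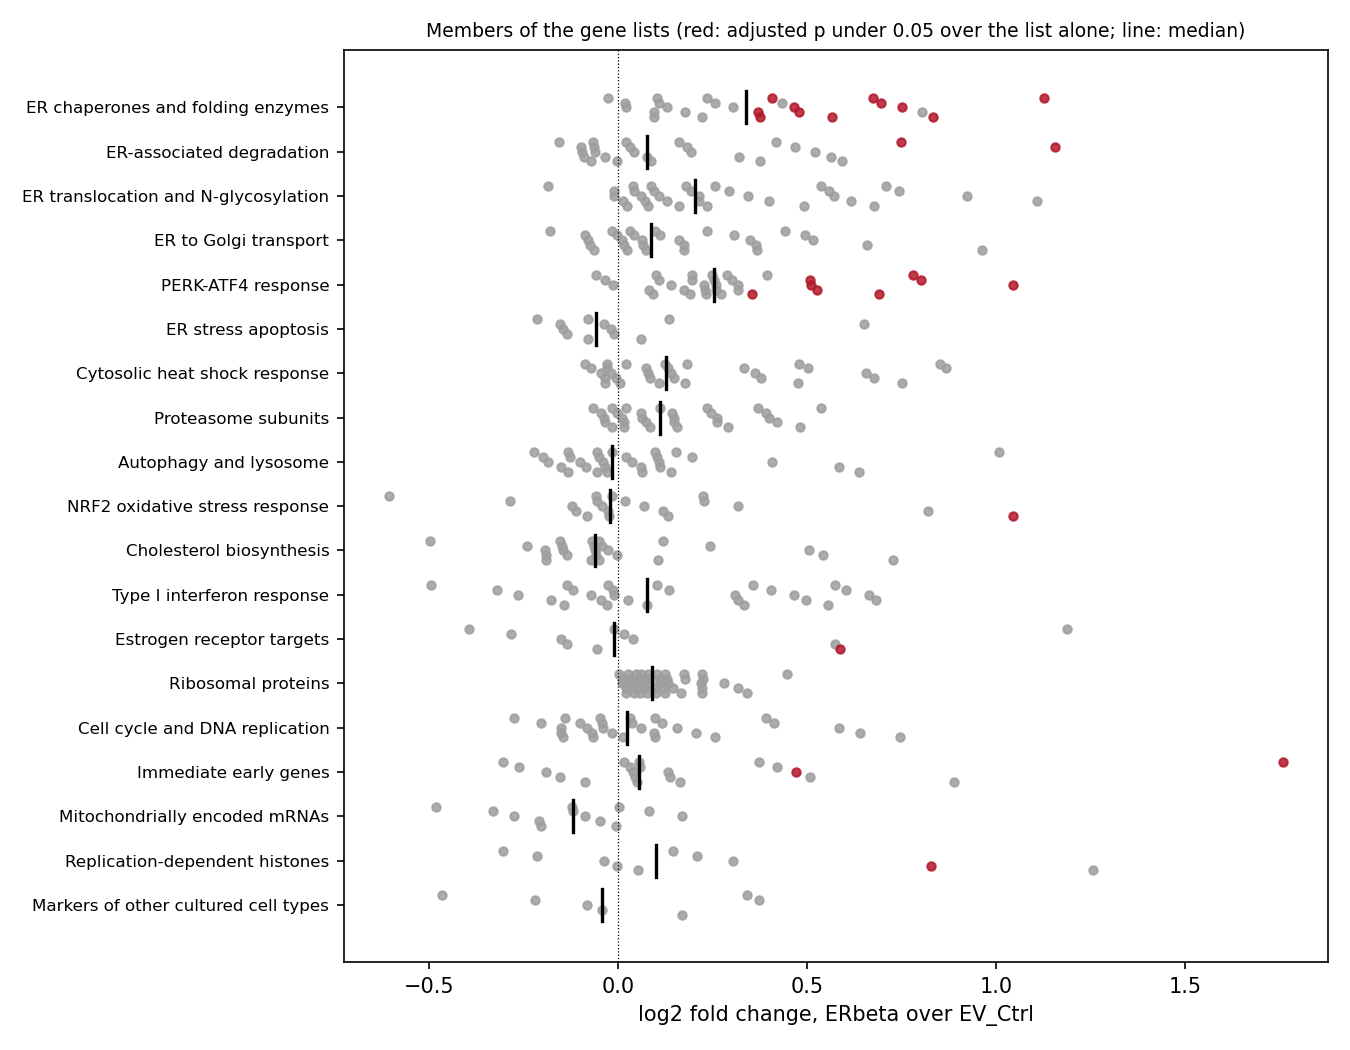
Log2 fold change of ERbeta over EV_Ctrl (horizontal axis) for each measured member of the 19 gene lists (rows), with 3 libraries per group; red points passed the threshold of 0.05 adjusted over the list alone and black lines are medians. The medians of ER chaperones (0.34) and of PERK-ATF4 targets (0.25) were the largest of the 19.

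Among the other 13 lists camera made 0 calls. Ribosomal protein genes were positive in 46 of 46 members with a median of 0.09 (adjusted p 0.107, adjusted p = 0.898 with an estimated correlation), a sign that turned in camera without EV_Ctrl 3. Camera called this list higher without ERbeta 1 (adjusted p 0.00676), without EV_Ctrl 1 (0.0315) and with GC correction (0.0101, adjusted p = 0.811 with an estimated correlation), and lower without both EV_Ctrl 1 and 3 (0.0066). The smallest p was that of RPS24 at 0.32 ± 0.18 (0.52 without EV_Ctrl 2, 0.15 without EV_Ctrl 3 and 0.10 after GC correction). Proteasome subunits had a median of 0.11 (adjusted p 0.0817, PSMD12 at 0.42 ± 0.14 and, after GC correction, at -0.06), with a mean log2 CPM of 7.34 in EV_Ctrl 2 inside the ERbeta range of 7.25 to 7.36 and 7.15 and 6.93 in EV_Ctrl 1 and 3. They were called higher without ERbeta 1 (0.0332) or EV_Ctrl 1 (0.0308). With all 6 libraries the estimated correlation was 0.555, with an adjusted p of 0.894. Immediate early genes, which respond to growth factors and stress, had a median of 0.06 (adjusted p 0.121). Adjusted over the list alone 2 of 21 rose, EGR1 at 1.76 ± 0.37 and JUN at 0.47 ± 0.10, and this count was 0 without ERbeta 1, ERbeta 2 or EV_Ctrl 1 and with the replicate block, 1 with library size only and 7 with GC correction. Camera called this list higher without ERbeta 3 (3.36e-05), EV_Ctrl 1 (0.0308) or EV_Ctrl 3 (0.016), without both EV_Ctrl 1 and 3 (7.73e-09) and with GC correction (adjusted p 4.44e-06, adjusted p = 0.339 with an estimated correlation). Replication-dependent histones had a median of 0.10 (adjusted p 0.163) and 1 of 10 rose adjusted over the list alone, H2BC5 at 0.83 ± 0.15, or 2 without EV_Ctrl 3. With GC correction camera called them higher (adjusted p 0.0344, adjusted p = 0.314 with an estimated correlation), and fry did so without it (0.0463). Mitochondrially encoded mRNAs had a median of -0.12 (adjusted p 0.173, MT-ND6 at -0.33 ± 0.25). Their mean log2 CPM was 9.79 in ERbeta 3 and 10.3 to 10.6 in the other libraries, and without ERbeta 2 the list was called lower (adjusted p 0.00437), as it was with GC correction (0.0276, adjusted p = 0.747 with an estimated correlation; 0.894 without GC correction). Without ERbeta 3 MT-ND6 was at -0.16, without EV_Ctrl 3 at -0.03 and after GC correction at -0.52.

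Lists of other stress and metabolic processes gave no call either. For ER stress apoptosis the median was -0.06 over 12 members (adjusted p 0.749), with PMAIP1, the BH3-only protein NOXA, at 0.65 ± 0.17 and, after GC correction, at 0.12. Autophagy and lysosome genes had a median of -0.02 over 31 members, a mean of 0.07 and a test direction upward (adjusted p 0.847), with ATG12 at 0.58 ± 0.19 and, after GC correction, at 0.09. NRF2 targets of the oxidative stress response had a median of -0.02, a mean of 0.08 and an upward test (adjusted p 0.685). Adjusted over the list alone 1 of 20 passed, SLC7A11, which is also a PERK-ATF4 target, and none passed without ERbeta 1, ERbeta 3, EV_Ctrl 1 or EV_Ctrl 3, while 3 did without ERbeta 2 and 2 without EV_Ctrl 2. With the replicate block or GC correction 0 passed. Cholesterol biosynthesis had a median of -0.06 over 25 members (adjusted p 0.431, STARD4 at 0.51 ± 0.19 and, after GC correction, at -0.22) and was called lower without both EV_Ctrl 1 and 3 (0.0347). With all 6 libraries and an estimated correlation its adjusted p was 0.894. Type I interferon genes had a median of 0.08 over 29 members (adjusted p 0.749, ISG20 at 0.36 ± 0.18), with a test direction that turned downward without ERbeta 3, EV_Ctrl 1 or EV_Ctrl 2. Cell cycle and DNA replication had a median of 0.02 over 30 members (adjusted p 0.841, CCNA2 at 0.39 ± 0.15 and, after GC correction, at 0.18).

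Estrogen receptor targets were included because the plasmid's name resembles that of estrogen receptor beta. Over 11 measured targets the median was -0.01, the mean 0.12 and the test upward with an adjusted p of 0.833. Adjusted over the list alone 1 rose, XBP1, at 0.59 ± 0.09, which is also a gene of the ER stress response, or 3 without EV_Ctrl 2 and 0 with GC correction. ESR2, the gene of that receptor, had 7, 2 and 2 reads in the ERbeta libraries and 3, 7 and 5 in EV_Ctrl, a pooled ratio of 0.754 with a counting interval of 0.313 to 1.76. ESR1 had 22 reads in ERbeta and 7 in EV_Ctrl, a pooled ratio of 3.23 (1.33 to 8.95). Both fell below the filter of edgeR's test, and in DESeq2 neither passed (adjusted p 0.892 for ESR2 and 0.469 for ESR1). Markers of other cultured cell types had a median of -0.04 over 7 measured members (adjusted p 0.894), with EPCAM at 0.37 ± 0.15 (0.57 without EV_Ctrl 2). Of the 24 symbols of that list only these 7 passed the filter.

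Genes outside the lists were chosen after their values were seen. LHFPL3-AS1, an antisense transcript, had 60 reads in ERbeta and 3 in EV_Ctrl, a pooled ratio of 20.6 with a counting interval of 6.70 to 102, and was the single call of limma-voom (adjusted p 0.047). Because the strand setting of the counting is unknown, its reads may include those of an overlapping gene. The liver amino acid enzyme gene TAT had 79 against 12 reads and the adjacent maltase genes MGAM and MGAM2 155 against 49 and 152 against 22. CFAP43 was at a log2 fold change of 1.47 ± 0.17, ARRDC3 at 1.5 ± 0.23 and RNF138, a ubiquitin ligase, at 1.03 ± 0.14, with DESeq2 adjusted p-values of 1.37e-05, 1.91e-05 and 1.37e-05. EIF2AK3, which encodes PERK itself, was at 0.55 ± 0.11 (DESeq2 adjusted p 0.0306), and FGF21, a secreted hormone and known ATF4 target, at 1.53 ± 0.30 from 46 against 16 reads (DESeq2 adjusted p 0.284). The single gene that DESeq2 called lower was KNDC1, at 3.51 ± 0.40 against 6.97 ± 0.77 CPM (DESeq2 adjusted p 0.0362). After GC correction RNF138 was at 0.49 and ARRDC3 at 1.05 in edgeR's test.

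The libraries differed in how level depended on GC content. Across genes, which are not independent replicates, Spearman's rho of the log2 fold change against transcript GC content was -0.607, and 0.019 after the correction. In the bin of genes with the lowest GC content, 26.7% to 39.3%, the median deviation from the gene's mean log2 CPM was 0.22, 0.17 and 0.49 in ERbeta 1 to 3, -0.50 in EV_Ctrl 1, 0.15 in EV_Ctrl 2 and -0.45 in EV_Ctrl 3. In the bin with the highest, 60.6% to 74.5%, it was -0.02, 0.08 and -0.31 in ERbeta 1 to 3 and 0.16, 0.01 and 0.13 in EV_Ctrl 1 to 3. With the GC correction edgeR's test again called 0 genes, with a smallest adjusted p of 0.0521 and 1717 genes at an unadjusted p under 0.05. With GC correction DESeq2 called 70 genes, of which 34 were among its 52 calls without correction, and limma-voom called 10. DESeq2 was given all 64299 genes without correction and the 16091 filtered genes with it. Its change in calls is therefore not the effect of the correction alone. With correction camera called 9 of the 19 lists in place of 6, and with an estimated correlation 1 in place of 0. The ER chaperone list then had an adjusted p of 1.24e-11, and adjusted p = 0.0259 with an estimated correlation, which was -0.007. The PERK-ATF4 list had 1.33e-17, and adjusted p = 0.178 with an estimated correlation.

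**Figure D3:**
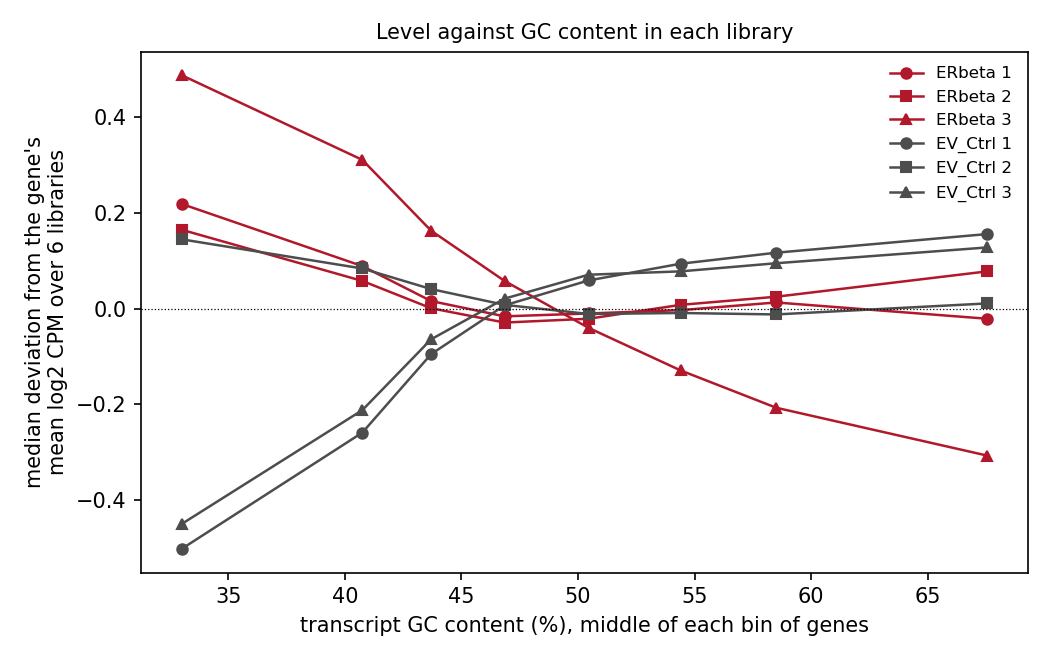
Median deviation of genes from their mean log2 CPM over the 6 libraries (vertical axis) in 8 bins of transcript GC content in percent (horizontal axis), 1 line per library, ERbeta in red and EV_Ctrl in grey. In the lowest bin EV_Ctrl 1 and 3 lay at -0.50 and -0.45, while EV_Ctrl 2, at 0.15, lay beside ERbeta 1 and 2.

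The authors' deposited table lists 421 genes with an adjusted p under 0.05, 373 higher and 48 lower in ERbeta. All 421 had the same direction in the test of the counts here, as did 98.6% of all tested genes, and 408 had an unadjusted p under 0.05 here. Across genes the log2 fold changes of the authors' deposited table and of edgeR correlated with a Pearson r of 0.942. Of the 52 genes that DESeq2 called here, 26 were called in the authors' deposited table and 20 have no adjusted p there, where 11150 genes have one. Deposited log2 fold changes lay closer to 0 than those of DESeq2 here. The median of their absolute values was 0.485 times that of DESeq2 for tested genes with a mean log2 CPM under 2 and 0.844 times for the others, so the sizes are not directly comparable. In the authors' deposited table HSPA5 was at a log2 fold change of 0.72 (adjusted p 3.59e-21), HERPUD1 at 1.01 (7.55e-12), DNAJB9 at 0.77 (0.00716), EIF2AK3 at 0.50 (0.00022) and ARRDC3 at 1.17 (4.48e-11), while DDIT3 was at 0.47 with an adjusted p of 0.0943 and XBP1 at 0.44 with 0.0798. Of the fixed lists, 13 ER chaperones, 4 members of ER-associated degradation, 4 of translocation and N-glycosylation and 1 PERK-ATF4 target were called higher in the authors' deposited table, and 0 cytosolic heat shock genes. Also called higher there were 2 immediate early genes and 1 member each of the ER to Golgi, ER stress apoptosis, proteasome, autophagy and NRF2 lists. The comparison computed here and the deposited table are not independent, although the latter also drew on reads outside the count table. The median GC content was 39.4% for the genes called higher in the authors' deposited table, 58.6% for those called lower and 48.5% for all tested genes. With GC correction of the counts 88.8% of the 421 had the same direction and 214 an unadjusted p under 0.05.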

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

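The GC tests of the list pattern and the position test of EV_Ctrl 2 were chosen after the results they bear on had been seen.

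The authors' deposited table gives a mean above 0 for 8079 genes that had 0 reads in each of the 6 libraries, the largest of these means being 1.61. In all, 38565 genes had a mean above 0 there and 30486 had reads here. A mean over these 6 libraries alone would be 0 for such genes, so the values in that table drew on reads outside this count table. The median standard error was 0.14 there and 0.212 in DESeq2 here (0.185 and 0.445 at a mean log2 CPM under 2, where deposited log2 fold changes also lay closer to 0), and whether added reads or shrinkage of the estimates lowered it was not tested. Which reads these were was not analysed here.

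Camera called ER chaperones and PERK-ATF4 targets higher in ERbeta, but with an estimated correlation the adjusted p was 0.201 and 0.299 (0.0259 and 0.178 with GC correction). In fry it was 0.00816 for each. A GC trend between libraries as the whole cause would take the larger of the adjusted camera p-values at the preset correlation to 0.05 or more when corrected, and it was then 1.24e-11. In counts thinned to a common total it was 4.96e-07. Splits that mixed the groups also gave small camera p-values at that correlation, so staying under 0.05 does not by itself argue against either cause. The median log2 fold changes were 0.34 for ER chaperones and 0.25 for PERK-ATF4, and 0.27 and 0.32 with GC correction, which thus did not remove them. The 10 splits of the 6 libraries are too few for a share under 0.05, with a camera p of the chaperone list of 4.76e-10 for the real split and 1.23e-05 as the smallest of the others (1 split as small, the real one included), and for PERK-ATF4 1.15e-08 and 2.34e-06. For the same reason the counts of called genes say no more, with 0 for the real split and 0 as the highest other in edgeR's test (10 splits as large) and 52 and 6 in DESeq2 (1 split as large). The transfected protein, the difference that the design names, and a difference in handling that ran along the groups both stay open and were not tested, and the labels give no batch.

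Without EV_Ctrl 2, 2324 genes were called, against 0 with it. A GC trend alone would remove most of them on correction, and 1650 were called. Higher calls went from 2198 to 1054 and lower calls from 126 to 596, and whether the same genes stayed called was not analysed. Counts thinned to a common total gave 2142, 1973 of them higher. A wrong label on EV_Ctrl 2 would put its GC-corrected level of the ER chaperone and PERK-ATF4 lists near that of ERbeta. On a scale from 0 (EV_Ctrl 1 and 3) to 1 (ERbeta) it lay at -0.016 (0.081 and -0.11 for each list, or 0.36 and -0.11 uncorrected). These lists were picked after they were called with EV_Ctrl 2 as a control, which favours such a position. Of genes named before the data were seen, HSPA5 was at 536 CPM there, 530 and 501 in EV_Ctrl 1 and 3 and 870 to 888 in ERbeta. HERPUD1, DDIT3 and XBP1, at 29.8, 28.2 and 84.3 CPM in EV_Ctrl 2, also lay below every ERbeta library (at least 57.1, 43.8 and 129). DNAJB9, at 20.9, lay between EV_Ctrl 1 and 3 (11.5 and 13.3) and ERbeta (30.7 to 37.8). Over the whole library EV_Ctrl 2 lay with ERbeta instead, at -12.2 on the first principal component after GC correction beside ERbeta 1 at -12, with EV_Ctrl 1 and 3 at 31.7 and 33.4, and its highest Pearson r was with ERbeta 2 (0.993). The values argue against depth as the whole cause and, by most of these stress genes named in advance, against a wrong label. They do not decide on GC, since higher calls fell on correction while lower calls rose. What set EV_Ctrl 1 and 3 apart, the shallowest libraries, stays open, and shared handling of that pair is a candidate explanation that was not tested.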

How the results depend on the processing

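The GC settings and the fit without EV_Ctrl replicates 1 and 3 were chosen after seeing the data. In edgeR's test the count of called genes was 0 with DESeq2 size factors, library size only, at least 1 CPM in all libraries, robust empirical Bayes, the replicate block, thinned counts, an adjusted p under 0.01, GC correction with and without the replicate block, and without EV_Ctrl 1 and 3. It was 51, all higher, without the low-count filter. The 0 at an adjusted p under 0.01 was fixed by the 0 under 0.05. DESeq2's test, given all 64299 genes, called 52 (51 higher, 1 lower), and limma-voom called 1 (higher). GC-corrected DESeq2, given the 16091 filtered genes, called 70 (66 higher, 4 lower) and GC-corrected limma-voom 10, all higher. The 4 lower genes of GC-corrected DESeq2 were CYREN, PRCP, RPL22P1 and ATXN7L3B, named after their values were seen. Leaving out 1 library gave 0 to 2324 genes, 0 to 2198 higher and 0 to 126 lower, the upper values without EV_Ctrl 2. Scaling by library size only moved the median log2 fold change of all genes from -0.012 to -0.104. With 6833442 reads in the shallowest library, depth limits the genes below the filter, ESR1 and ESR2 among them.

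Whether replicate numbers pair the samples is not stated in the labels, and the values do not settle it. Without GC correction, the deviations of same-numbered libraries from their group means correlated at 0.233, -0.136 and -0.152, and each ERbeta library matched best with another number. In edgeR's test the genes at an unadjusted p under 0.05 went from 2018 to 1814 with the replicate block. With GC correction they went from 1717 to 2043. Without GC correction, the replicate block left 0 genes called and took the ER-associated degradation and the ER to Golgi lists to an adjusted p of 0.0579 each in camera. It changed no other list's call there. Over all alternatives, 238 values of lists and 920 of named genes kept their direction and their side of the threshold, and 18 and 98 newly passed it in the same direction. As 0 genes passed in the main test, the named genes that kept their side were those that again did not pass, and none could stop passing. Of the lists 29 values no longer passed, and 19 values of lists and 34 of named genes turned.

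Fry, which does not compare members with other genes, gave an adjusted p of 0.00816 each for ER chaperones, ER-associated degradation and PERK-ATF4. For the main lists in camera, an estimated correlation gave adjusted p-values of 0.201 (ER chaperones), 0.299 (ER-associated degradation), 0.299 (PERK-ATF4) and 0.894 (heat shock). With GC correction as well, ER-associated degradation was at 0.24, PERK-ATF4 at 0.178 and heat shock at 0.567. With library size only ER-associated degradation was at 0.122, fry gave heat shock 0.207, and without EV_Ctrl 1 and 3 heat shock was at 0.541. Leaving out 1 library gave ranges of 5.41e-09 to 0.000336 for ER chaperones, 0.0242 to 0.353 for ER-associated degradation, 5.41e-09 to 0.0581 for PERK-ATF4 and 0.00453 to 0.119 for heat shock, upward each time. The same direction as in the deposited comparison was found for 98.6% of tested genes and 100% of its called genes.

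The following signs turned, and the cause was not tested. Under GC correction in edgeR, in DESeq2, in limma-voom and in edgeR with the replicate block, the log2 fold changes were 0.079, 0.079, 0.096 and 0.081 for HSPA1A, 0.095, 0.095, 0.103 and 0.098 for HSPA1B, 0.054, 0.053, 0.053 and 0.054 for DNAJB1, -0.062, -0.06, -0.055 and -0.061 for PSMD12, and -0.22, -0.219, -0.201 and -0.214 for STARD4. In edgeR, DESeq2 and edgeR with the block, DNAJB11 was at -0.024, -0.024 and -0.019 and BET1 at -0.004, -0.001 and -0.004. Without EV_Ctrl 1 and 3, RPS24 was at -0.005, MT-ND6 at 0.019, HSPA1A at 0.231 and HSPA1B at 0.213. Leaving out 1 library gave -0.196 to 0.003 for HSPA1A, -0.152 to 0.027 for HSPA1B and -0.073 to 0.009 for DNAJB1. None of these genes passed the threshold there.

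The cause of the following turns was not tested either. Among the other lists, camera's direction turned downward with library size only for autophagy and for cell cycle (adjusted p 1 each). Without EV_Ctrl 1 and 3 it turned downward for proteasome subunits (0.425), ribosomal proteins (0.0066, past the threshold) and cell cycle (0.541). Markers of other cell types turned upward in fry (0.7), with GC correction (0.782; 0.801 with the replicate block; 0.827 with an estimated correlation) and without EV_Ctrl 1 and 3 (0.31). Leaving out 1 library turned the direction at least once for the following lists, whose adjusted p ranged from 0.502 to 0.992 for autophagy, 0.0537 to 0.992 for type I interferon, 0.00676 to 0.973 for ribosomal proteins, 0.562 to 0.973 for cell cycle, 3.36e-05 to 0.944 for immediate early genes, 0.00437 to 0.523 for mitochondrially encoded mRNAs and 0.809 to 0.99 for markers of other cell types.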

Other observations

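The tests of the pattern below were written after the pattern was noticed and before their own results were seen, except that the GC correction itself was chosen after seeing the data.

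Of 3617 tested genes with a mean log2 CPM under 2, 78 were at least 2-fold higher in ERbeta without overlap between groups and 13 at least 2-fold lower, among the higher ones TAT and MGAM, both chosen after their values were seen. If a GC trend between libraries were the whole cause, the surplus would go with the correction, and 62 were then higher and 17 lower. If unequal depth were, it would go in counts thinned to a common total, where 96 were higher and 46 lower. A surplus of higher genes stayed in both, but with thinning the lower genes rose from 13 to 46, so depth may be part of the cause. Splits that mixed the groups also gave such genes in 1 direction. A surplus that stays therefore does not by itself argue against either cause. The 10 splits are too few for a share under 0.05, with 78 genes for the real split and 34 as the highest of the others (1 split as large, the real one included). What causes the pattern stays open, and a difference between the preparations in genomic DNA or unspliced RNA was not tested.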
